A study of Homo sapiens with 70 samples.

How the data were processed

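Gene expression was measured in bone marrow samples taken at diagnosis and at first marrow relapse, on 70 arrays, 35 per time point. Per the labels' protocols, total RNA was extracted from cryopreserved cells, amplified in a double amplification protocol, labelled with biotin and hybridised as fragmented cRNA. The deposited values are intensity values on a linear scale, 1 summarised signal per probe set and array, made with MAS5 per the submitters' processing notes. The MAS5 version and its scaling target are not given in the sources used here. Detection calls were not used here. The disease and its lineage are not in the labels; the study is known, from outside the labels, to concern acute lymphoblastic leukaemia, and the gene lists were chosen for that disease.

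The table held 22283 probe sets, 68 of them controls, and 6 values of 0. The mean signal of an array after trimming 2% of the values at each end ran from 20.8 to 149 signal units, with a coefficient of variation of 46.3%. This exceeded the limit of 10% set in advance, so each array was scaled to a common trimmed mean of 67.2. Values were then expressed as log2(value + 2.65), where the pseudocount was the 10th percentile of all scaled values. All log2 differences below are on this scale, which understates the change of dim genes. Arrays carry no read depth, and the precision is limited by their number.

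Of the probe sets, 19065 had 1 gene symbol in the platform annotation, 1043 had several and 2107 were not listed there. Symbols were updated through the Entrez gene ID with a table of GRCh38.p14 genes, which matched 19053 of the single-gene probe sets and was used for names alone. No genome coordinates are given, since the values belong to probe sets. Control probe sets and 31 probe sets of XIST, TSIX and Y-linked genes were left out. Probe sets were kept if their mean over all arrays reached the median (50th percentile) of the non-control probe sets, which left 11108. Where a gene had several, the probe set of highest mean stood for it, and 7086 genes were tested. Among the named genes, the probe sets of COX4I1 and PSMB2 differed in sign, with 2 of 3 and 1 of 2 on the side reported. Of the 28 named genes with several probe sets, 16 others had probe sets of the same sign more than 1.5 times apart, such as RRM1 (0.019 to 0.39), ATP5PO (0.067 to 0.41), NR3C1 (-0.33 to -0.094) and PSMD4 (0.20 to 0.63).

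Relapse was compared with diagnosis in limma 3.58.1 under R 4.3.3, with lmFit and eBayes with an intensity trend, Benjamini-Hochberg adjustment over all tested genes and a threshold of adjusted p 0.1. The fit was unpaired. The design text states that the same patients were sampled at both times, but no label states which diagnosis and relapse arrays belong together, so patient differences stay in the residual spread. Of 28 gene lists, 27 had at least 5 tested members and were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. The marrow stroma and endothelium list had 4 tested members and was not tested. Camera with a correlation estimated from the data and fry were run as alternatives, and fry's directional p was used. A two-sided permutation of the arrays (100000 resamples) on the mean of a list's members was added after the data were seen. P-values here weigh a difference against the spread between arrays. The main tests treat the arrays as independent, although the same patients were sampled at both times.

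The distance of each array to its group centre was 1 minus its Pearson correlation with the mean of the other arrays of its group. The RNA degradation index was the mean log2 ratio of the 3-prime to the 5-prime control probe sets of GAPDH and ACTB. Both were compared by a two-sided permutation test of 100000 resamples. An array was called outlying if its median correlation with the other arrays lay more than 3 median absolute deviations below that of the median array; there was 1, from the relapse group. A set of 6 relapse arrays, called bright here, lay above the largest gap in trimmed mean signal and was left out in an added setting. Their trimmed means, 148.1 to 148.8, were nearly equal, and the sources do not give whether these arrays were scaled apart from the others. The array brightness covariate was the log2 trimmed mean of the deposited values, so it cannot tell such scaling from signal. Since no diagnosis array lay above the gap, this set and the relapse group cannot be told apart within it. A further added setting left out the 8 arrays whose B-precursor or MHC class II score, the mean of the list's members, lay more than 3 median absolute deviations below the median array. No pair of arrays was a duplicate, the highest correlation being 0.924.

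The gene lists and the rule for naming genes were fixed before the data were examined, as were the tests and settings other than those said to have been added or chosen after the data were seen. The rule took the 12 largest differences per direction past the threshold, or, with fewer than 10 past it, the genes of smallest p up to 10. It added the 4 members of smallest p, in the list's direction, of each list past the threshold. For other lists it added up to 2 members past adjusted p 0.1. It also took genes fixed by name whatever their result, some of which are not reported here. Genes named outside the rule are said to be so.

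The gene test was tested on simulated data, in 10 draws that kept the real arrays' spread and added a difference to 200 of 7086 genes. It recovered 58.1% of genes changed by 0.5 on the log2 scale and 93.7% of those changed by 1, with 7% false among the calls. With no difference added, camera at the preset correlation called a mean of 7 and at most 14 of the 27 lists, while camera with the estimated correlation and fry called a mean of 0. The alternatives covered normalization (quantile, median centring), pseudocount, dim-probe filter, probe set choice, array weights, a rank test, covariates, outlying arrays, replicate blocks and each array left out in turn. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.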

Results

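Bone marrow from 35 patients was profiled at diagnosis and at first marrow relapse, with 35 arrays per time point. The comparison asks which genes and gene groups differ in level between the 2 time points. The trimmed mean signal of an array was 59.8 ± 19.4 at diagnosis (SD, n = 35, range 26.9 to 105) and 74.6 ± 38.4 at relapse (SD, n = 35, range 20.8 to 149). Its log2 value differed by 0.22 ± 0.15 (SE, two-sided permutation p = 0.132) before the arrays were scaled to a common mean. Of the relapse arrays, 6 stood apart, at 148.1 to 148.8, above all 35 diagnosis arrays and the other relapse arrays; without them the relapse mean was 59.3 ± 19.6 (SD, n = 29). Differences below are log2 relapse minus diagnosis ± SE, with 35 arrays per group.

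As groups, genes of mitosis, oxidative phosphorylation and the granulocyte lineage rose at relapse, and genes induced by glucocorticoids fell. With an estimated correlation none of the 4 lists passed camera, with adjusted p = 0.102 for each of the first 3 and adjusted p = 0.187 for the glucocorticoid list. The mitosis and G2/M genes lay higher by a mean of 0.42 ± 0.13, the oxidative phosphorylation genes by 0.19 ± 0.066 and the granulocyte markers by 0.56 ± 0.20. The glucocorticoid-induced genes differed by -0.39 ± 0.15. The 4 lists passed camera at the preset correlation, fry and the permutation of arrays, though not camera with an estimated correlation, with permutation adjusted p = 0.0440, 0.0440, 0.0440 and 0.09997 in that order. Without the 6 bright relapse arrays, a set chosen after the data were seen, the first 3 passed by permutation (adjusted p = 0.013, 0.0472 and 0.0923) and the glucocorticoid list did not (-0.37 ± 0.17, adjusted p = 0.12). Camera at the preset correlation called 16 of 27 lists, 10 higher and 6 lower, against 0 with an estimated correlation, 4 by fry and 4 by permutation. Since the preset test also called a mean of 7 lists in simulated data with no difference, a list past that test alone is given below by its values.

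**Figure D1:**
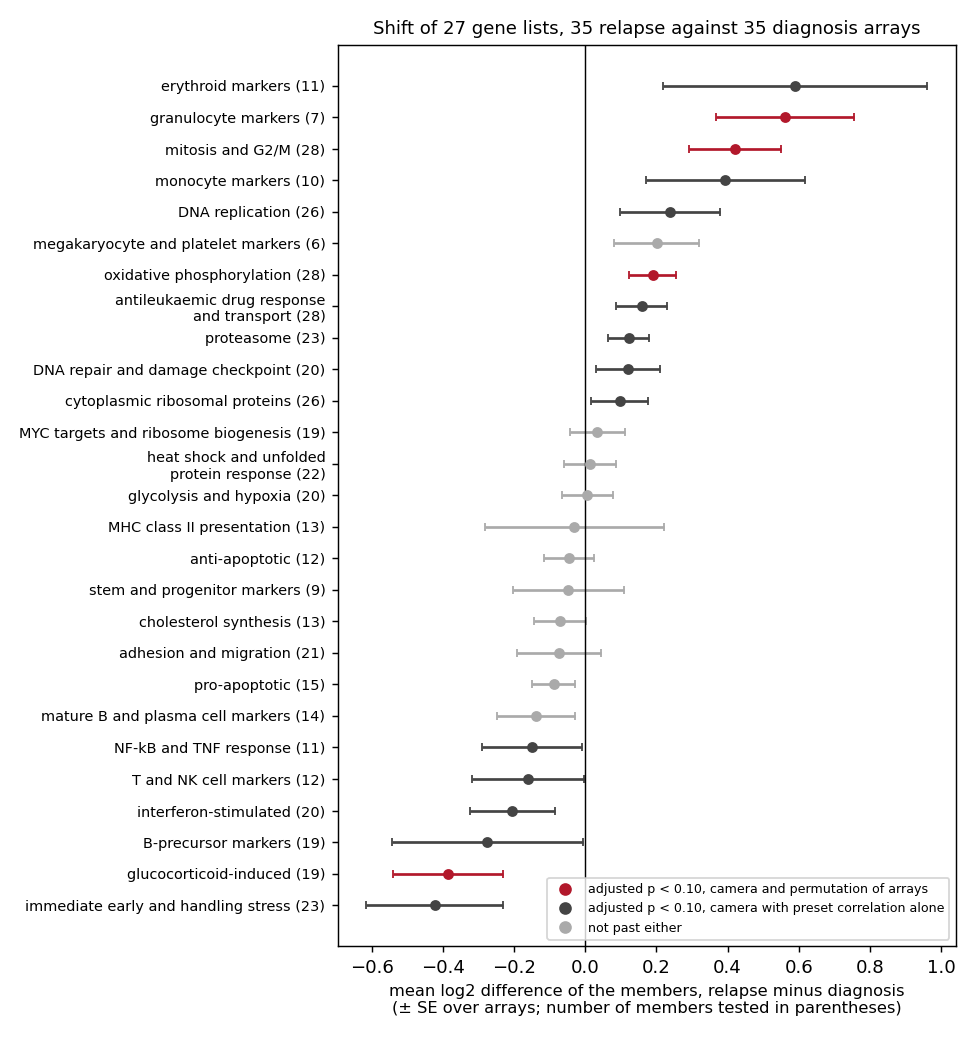
Mean log2 difference (relapse minus diagnosis) of the members of each of 27 gene lists on the horizontal axis, with bars of ± SE over the arrays and the number of tested members in parentheses. Red points are the 4 lists past adjusted p 0.1 by both camera at the preset correlation and permutation of the arrays, with means of 0.56 for granulocyte markers, 0.42 for mitosis and G2/M, -0.39 for glucocorticoid-induced genes and 0.19 for oxidative phosphorylation.

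Of 28 tested mitosis and G2/M genes, 26 had a positive difference and 20 of these had an unadjusted p under 0.05. By limma, 0 passed adjusted p 0.1 over all genes, while 21 passed when adjusted over the list alone. The mean of the list lay above the diagnosis median in 24 of 35 relapse arrays (camera adjusted p = 1.84e-17; adjusted p = 0.102 with an estimated correlation; fry adjusted p = 0.0411). BIRC5 (survivin, an inhibitor of apoptosis that also acts in chromosome segregation) had a level of 6.98 ± 0.80 at diagnosis and 7.73 ± 0.82 at relapse (SD), a difference of 0.75 ± 0.19 (adjusted p = 0.122). Without the 6 bright relapse arrays BIRC5 differed by 0.86 and was the 1 gene past the threshold (adjusted p = 0.0646). TOP2A, the topoisomerase targeted by anthracyclines and etoposide, differed by 0.78 ± 0.23 (adjusted p = 0.22). The kinetochore motor CENPE differed by 0.76 ± 0.21 and the microtubule depolymerase KIF2C by 0.55 ± 0.16. MKI67, the gene of the Ki-67 proliferation antigen, differed by 0.28 ± 0.12 (adjusted p = 0.441). Over all probe sets of a gene the difference ran from 0.23 to 0.75 for BIRC5, 0.27 to 0.78 for TOP2A, 0.076 to 0.55 for KIF2C and 0.28 to 0.81 for MKI67.

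DNA replication genes had a mean difference of 0.24 ± 0.14, with 25 of 26 positive and 4 at an unadjusted p under 0.05. They passed camera at the preset correlation (adjusted p = 3.95e-06) but had adjusted p = 0.377 with an estimated correlation. The ribonucleotide reductase subunit RRM1 differed by 0.39 ± 0.14, the helicase subunit MCM7 by 0.38 ± 0.14, the licensing factor CDT1 by 0.47 ± 0.20 and GINS1 by 0.48 ± 0.23. The antileukaemic drug response and transport list, which shares RRM1, RRM2, TYMS and TOP2A with the cell cycle lists, had a mean of 0.16 ± 0.071, 24 of 28 positive (adjusted p = 0.000955; adjusted p = 0.202 with an estimated correlation). Within it, RRM2 differed by 0.45 ± 0.24 and SLC29A1, a nucleoside transporter that carries cytarabine, by 0.40 ± 0.21. DNA repair and damage checkpoint genes had a mean of 0.12 ± 0.089, with 16 of 20 positive (adjusted p = 0.00949; adjusted p = 0.396 with an estimated correlation), and a mean of -0.071 in the 40 arrays whose label numbers lie 43 apart. FANCI, of the Fanconi anaemia pathway, differed by 0.47 ± 0.16, the end-joining factor XRCC5 by 0.19 ± 0.083, ERCC1 by 0.26 ± 0.13 and XRCC6 by 0.16 ± 0.098. Adjusted over the list alone, 0 replication genes, 2 drug response genes (TOP2A, RRM1) and 1 repair gene (FANCI) passed, and 0 of any of these lists passed over all genes. At an unadjusted p under 0.05 there were 4, 2 and 3 genes in the 3 lists.

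The rise of oxidative phosphorylation genes was small and broad, with 26 of 28 tested members positive and the list mean above the diagnosis median in 28 of 35 relapse arrays (adjusted p = 0.102 with an estimated correlation). By limma, 8 had an unadjusted p under 0.05, and 0 passed adjusted p 0.1 over all genes or adjusted over the list alone. The ATP synthase subunit ATP5PO differed by 0.41 ± 0.14, the complex I subunits NDUFV1 and NDUFA1 by 0.28 ± 0.11 and 0.25 ± 0.10, and the cytochrome c oxidase subunit COX4I1 by 0.26 ± 0.11, with 1 of the 3 COX4I1 probe sets of opposite sign. With array brightness as a covariate, the list had fry adjusted p = 0.104. Proteasome genes had a mean of 0.12 ± 0.058, 20 of 23 positive (adjusted p = 0.000505; adjusted p = 0.202 with an estimated correlation), with PSMD14 at 0.49 ± 0.17, PSMB4 at 0.19 ± 0.090, PSMB2 at 0.25 ± 0.13 and PSMD4 at 0.24 ± 0.13. Cytoplasmic ribosomal protein genes had a mean of 0.096 ± 0.081, 24 of 26 positive (adjusted p = 0.00194; adjusted p = 0.509 with an estimated correlation), with RPL32 at 0.31 ± 0.11, RPS23 at 0.21 ± 0.089, RPL11 at 0.25 ± 0.14 and RPS3 at 0.24 ± 0.14. Each of these 2 lists held 2 genes with an unadjusted p under 0.05 and 0 past the threshold when adjusted over the list alone.

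All 7 tested granulocyte markers, of 22 on the list, were positive, and the list mean lay above the diagnosis median in 23 of 35 relapse arrays (adjusted p = 0.102 with an estimated correlation). MMP9, a gelatinase stored in neutrophil granules, differed by 0.99 ± 0.25 (adjusted p = 0.125), the defensin DEFA4 by 0.95 ± 0.30, myeloperoxidase (MPO) by 0.90 ± 0.41 and the receptor CSF3R by 0.34 ± 0.19. Over all genes 0 passed by limma, 3 had an unadjusted p under 0.05, and 3 passed when adjusted over the list alone (MMP9, DEFA4, MPO). Erythroid markers had a mean of 0.59 ± 0.37, with 11 of 11 positive and 2 at an unadjusted p under 0.05 (adjusted p = 0.000198; adjusted p = 0.385 with an estimated correlation), and a mean of -0.020 in the 20 arrays whose label numbers occur in both groups. Those 20 arrays hold all 6 bright relapse arrays. BLVRB, the single erythroid gene past the threshold when adjusted over the list alone, differed by 1.10 ± 0.39, the anion exchanger SLC4A1 by 0.95 ± 0.40, and the globins HBB and HBD by 0.75 ± 0.49 and 0.68 ± 0.48. Monocyte markers had a mean of 0.39 ± 0.22, with 8 of 10 positive and 2 at an unadjusted p under 0.05 (adjusted p = 0.00768; adjusted p = 0.411 with an estimated correlation). S100A8, a calprotectin subunit, differed by 1.35 ± 0.47 and was the 1 monocyte gene past the threshold when adjusted over the list alone; S100A12 differed by 0.52 ± 0.25, FCN1 by 0.48 ± 0.30 and VCAN by 0.51 ± 0.34.

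Genes induced by glucocorticoids fell, with 18 of 19 tested members negative and the list mean below the diagnosis median in 24 of 35 relapse arrays (adjusted p = 0.187 with an estimated correlation). The chemokine receptor CXCR4 differed by -0.76 ± 0.27, the phosphatase DUSP1 by -0.72 ± 0.27, TSC22D3 (GILZ) by -0.70 ± 0.32 and PIK3IP1 by -0.61 ± 0.29. NR3C1, the glucocorticoid receptor gene, differed by -0.33 ± 0.18 (adjusted p = 0.619). Over all genes 0 passed by limma, 6 had an unadjusted p under 0.05, and 2 passed when adjusted over the list alone (CXCR4, DUSP1). The list had fry adjusted p = 0.0793, which was 0.185 with array brightness as a covariate and 0.103 without the 6 bright relapse arrays, and it passed in 54 of 70 fits that each left out 1 array. Its mean turned to 0.031 in the 20 arrays whose label numbers occur in both groups, a subset that holds all 6 bright relapse arrays. The highest scores of the list were in diagnosis replicates 16 (1.63), 8 (1.24) and 2 (1.17). In diagnosis replicates numbered from 17 on they reached at most 0.75.

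Immediate early genes, which many cells induce within minutes of a stimulus or of handling, had a mean of -0.42 ± 0.19. Of 23 tested, 21 were negative and 10 had an unadjusted p under 0.05, while 0 passed over all genes by limma and 10 passed when adjusted over the list alone. The list passed camera at the preset correlation (adjusted p = 3.54e-07) but had adjusted p = 0.202 with an estimated correlation and 0.134 by permutation. Its highest scores were in diagnosis replicates 6 (2.76), 5 (2.26), 7 (1.65) and 16 (1.61). In diagnosis replicates numbered from 17 on they reached at most 0.72. JUN differed by -0.71 ± 0.26, the mRNA decay factor ZFP36 by -0.46 ± 0.17 and KLF4 by -1.10 ± 0.45; DUSP1 is on this list too. NF-kB and TNF response genes had a mean of -0.15 ± 0.14, with 10 of 11 negative and 0 at an unadjusted p under 0.05 (adjusted p = 0.0125; adjusted p = 0.377 with an estimated correlation), and a mean of 0.17 in the 40 arrays whose label numbers lie 43 apart. NFKBIE differed by -0.27 ± 0.14, TNFAIP3 by -0.48 ± 0.27, NFKB1 by -0.26 ± 0.16 and TNF by -0.28 ± 0.19. Interferon-stimulated genes had a mean of -0.21 ± 0.12, with 17 of 20 negative and 2 at an unadjusted p under 0.05 (adjusted p = 0.00326; adjusted p = 0.377 with an estimated correlation). TRIM22 differed by -0.54 ± 0.20, XAF1 by -0.51 ± 0.21, IRF9 by -0.40 ± 0.21 and IFI6 by -0.42 ± 0.29, and 0 genes of these last 2 lists passed when adjusted over the list alone.

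**Figure D2:**
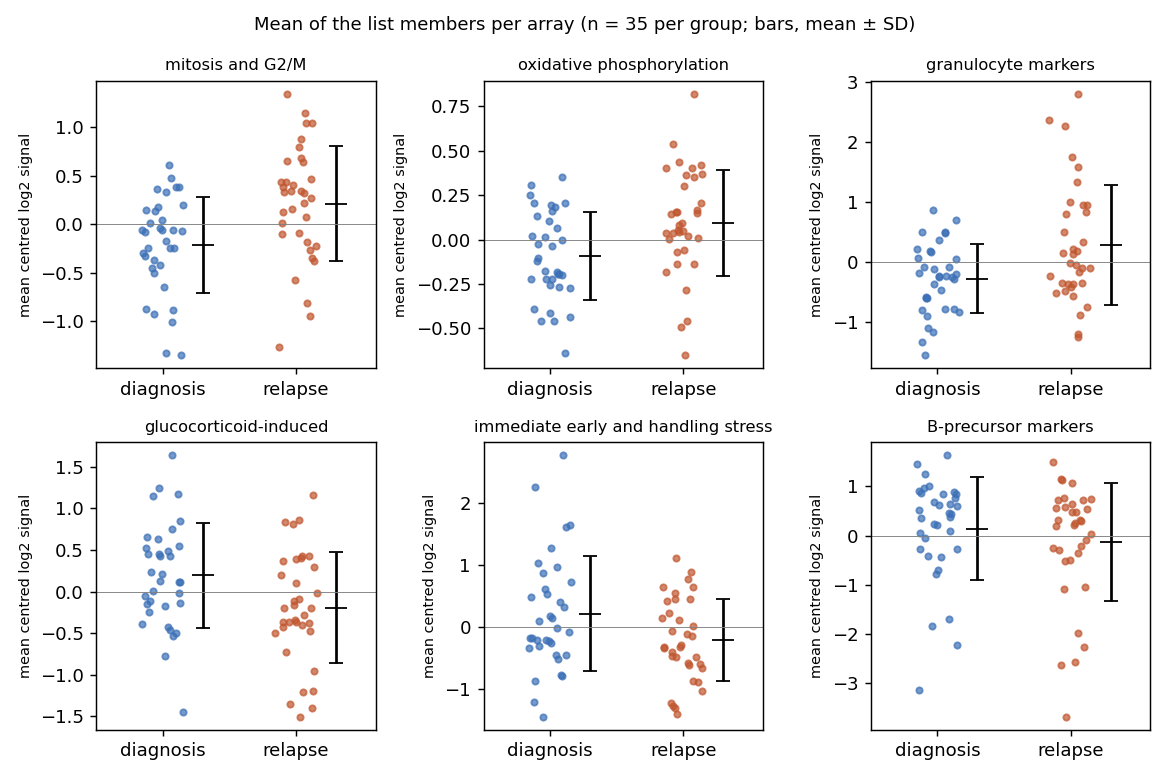
Mean log2 signal of the list members in each array, centred on the mean of all 70 arrays (vertical axis), for 6 gene lists, with the 35 diagnosis and 35 relapse arrays as points and the group mean ± SD as bars. The groups overlap in every panel, with means 0.42 apart for mitosis and G2/M, 0.56 for granulocyte markers and -0.39 for glucocorticoid-induced genes.

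B-precursor markers had a mean of -0.28 ± 0.27, with 16 of 19 negative (adjusted p = 0.0309; adjusted p = 0.547 with an estimated correlation). In the 20 arrays whose label numbers occur in both groups the mean had the opposite sign, 0.94 (camera adjusted p = 1.54e-07 at the preset correlation). Those 20 arrays hold all 6 bright relapse arrays. They also hold diagnosis replicates 4, 12 and 38, with B-precursor scores of -3.14, -2.22 and -1.84, but none of the 5 low-score relapse arrays described below. Over all arrays, the call was lost without relapse replicate 58, 63 or 69 (means of -0.20, -0.20 and -0.17; adjusted p = 0.138, 0.167 and 0.237). Without the 8 arrays of low B-precursor or MHC class II score, 3 from diagnosis and 5 from relapse and chosen after the data were seen, the mean was -0.099 ± 0.17 (adjusted p = 0.483). CD79A, part of the B cell receptor complex, differed by -0.45 ± 0.22, CD72 by -0.71 ± 0.39, CD9 by -0.86 ± 0.57 and CD24 by -0.74 ± 0.54. T and NK cell markers had a mean of -0.16 ± 0.16, with 9 of 12 negative (adjusted p = 0.0958; adjusted p = 0.526 with an estimated correlation). Camera at the preset correlation called that list in 33 of 70 fits that each left out 1 array, with a highest adjusted p of 0.305. The granzymes GZMB and GZMA differed by -0.54 ± 0.30 and -0.49 ± 0.33, perforin (PRF1) by -0.25 ± 0.18 and CD3E by -0.19 ± 0.13. At an unadjusted p under 0.05 there were 1 B-precursor gene and 0 T and NK genes, and 0 passed over all genes or when adjusted over the list alone.

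The other 11 lists did not pass camera at the preset correlation over all arrays. Mature B and plasma cell markers had a mean of -0.14 ± 0.11 (adjusted p = 0.153), megakaryocyte and platelet markers 0.20 ± 0.12 (0.209), pro-apoptotic genes -0.089 ± 0.061 (0.37) and anti-apoptotic genes -0.045 ± 0.070 (0.555). MYC targets and ribosome biogenesis genes had a mean of 0.034 ± 0.077 (adjusted p = 0.37), adhesion and migration genes -0.073 ± 0.12 (0.406) and cholesterol synthesis genes -0.071 ± 0.073 (0.406). Heat shock and unfolded protein response genes had a mean of 0.013 ± 0.073 (adjusted p = 0.544), MHC class II genes -0.031 ± 0.25 (0.612) and stem and progenitor markers -0.048 ± 0.16 (0.775). In the 20 arrays whose label numbers occur in both groups the MHC class II mean was 1.16 (camera adjusted p = 2.61e-06 at the preset correlation). Those 20 arrays hold all 6 bright relapse arrays. They also hold the 3 diagnosis arrays of low B-precursor or MHC class II score, but none of the 5 such relapse arrays. Glycolysis and hypoxia genes had a mean of 0.0059 ± 0.072 and a median of -0.030, so that these differed in sign (adjusted p = 0.81). Adjusted over the list alone, the adhesion list held 2 lower genes and the heat shock list 1 higher gene, the other 9 lists 0, and over all genes limma called 0, with 0 to 3 genes per list at an unadjusted p under 0.05. The 3 were VIM (-0.70 ± 0.24), CXCR4 and HSP90B1 (0.40 ± 0.12), of which VIM and HSP90B1 were named after their values were seen.

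Among single genes, the 10 of smallest p with a positive difference included the cytochrome c oxidase subunit COX7C (0.54 ± 0.12), the pyruvate dehydrogenase subunit PDHA1 (0.58 ± 0.14), the histone-citrullinating enzyme PADI4 (1.09 ± 0.27), the mitotic kinesins KIF18B (0.72 ± 0.18) and KIFC1 (0.69 ± 0.17), BIRC5, the prolyl isomerase FKBP2 (0.94 ± 0.24) and MMP9. The adaptor subunit AP2S1 (0.35 ± 0.094) and the mitochondrial calcium uniporter regulator MCUR1 (0.44 ± 0.12) completed the 10. The 10 with a negative difference were led by S1PR1, a receptor that guides lymphocyte egress, at 5.62 ± 1.08 at diagnosis and 4.66 ± 0.79 at relapse (SD), a difference of -0.96 ± 0.22. The others were MGAT2 (-0.56 ± 0.14), THUMPD1 (-0.53 ± 0.13), PRPF18 (-0.53 ± 0.13), ZBTB10 (-0.96 ± 0.26), GCKR (-0.54 ± 0.14), the linker histone H1-2 (-0.94 ± 0.25), TSC22D2 (-0.56 ± 0.15), RNF6 (-0.61 ± 0.17) and TRAF6 (-0.49 ± 0.14). None of these 20 genes passed the threshold in the unpaired fit, where their adjusted p ran from 0.122 to 0.196. With a replicate block on label numbers 43 apart, a pairing that no label states, BIRC5, PDHA1, MMP9, KIFC1, ZBTB10 and H1-2 passed (limma adjusted p from 0.0112 to 0.0967). The others did not.

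**Figure D3:**
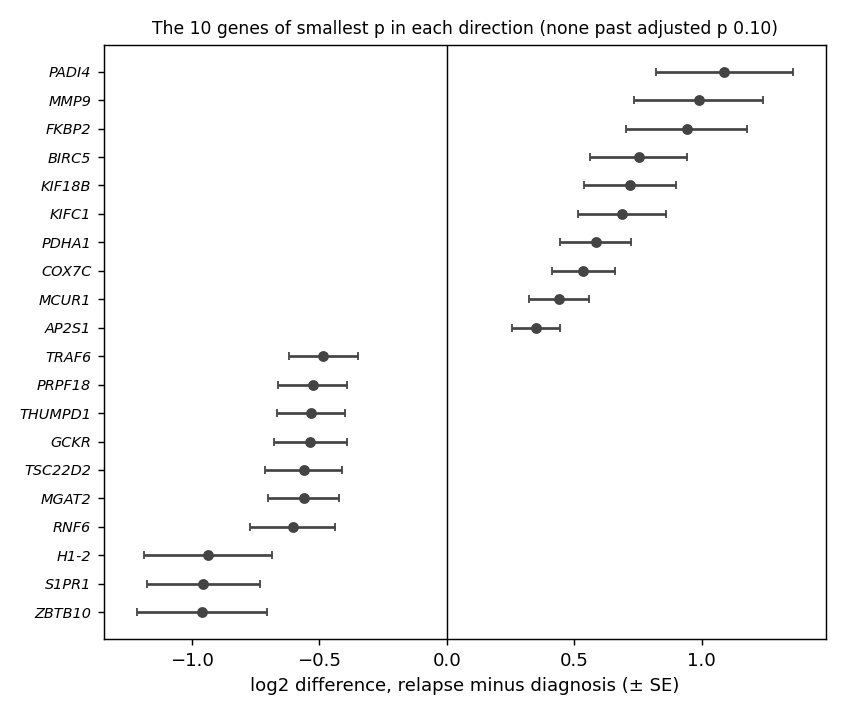
Log2 difference (relapse minus diagnosis, horizontal axis) with bars of ± SE for the 10 genes of smallest p in each direction, 35 arrays per group. PADI4 at 1.09 lies farthest from 0 among the positive differences and ZBTB10 at -0.96 among the negative ones, and no gene shown passed adjusted p 0.1 in this unpaired fit.

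Across the 7086 genes tested in the unpaired limma fit, 0 were higher and 0 lower at relapse at adjusted p 0.1, with a smallest adjusted p of 0.122. At an unadjusted p under 0.05 there were 326 higher and 311 lower genes, 637 in all, where 354 would be counted with no difference between independent genes; 11 of 100 splits of the arrays, the real one included, gave at least 637. A Wilcoxon rank-sum test also called 0 genes in either direction, with 335 higher and 298 lower at an unadjusted p under 0.05. The median SE of a log2 difference was 0.16. In simulated data with this spread, where 200 genes were changed by 0.5 or 1 together, 58.1% of genes changed by 0.5 were recovered. With fewer changed genes the adjusted threshold would be harder to pass, so this share is not the power of the real comparison. Array weights or the RNA degradation index as a covariate each gave 6 higher and 3 lower genes past the threshold, and a pseudocount at the 25th percentile gave 7 and 4, all 11 among the genes named here. A replicate block on label numbers 43 apart, a pairing that no label states, took 17 genes named here past the threshold, against 1 without the block on the same arrays. The count of 0 in the unpaired fit therefore does not show that no gene differs. Of the 70 fits that each left out 1 array, 10 called genes, at most 10 higher and 7 lower, without diagnosis replicate 38.

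Of the genes fixed by name, the drug target TYMS (thymidylate synthase) differed by 0.26 ± 0.26, the nucleotidase NT5C2 by 0.096 ± 0.14 and the mismatch repair gene MSH6 by -0.031 ± 0.18. Asparagine synthetase (ASNS) differed by -0.022 ± 0.28, the lymphoid polymerase DNTT by -0.13 ± 0.46, CD34 by 0.003 ± 0.18 and CD3D by 0.028 ± 0.36. Their adjusted p ran from 0.823 to 0.998. The signs of NT5C2, MSH6, ASNS, DNTT, CD34 and CD3D turned in some settings.

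The arrays of both groups lay at a like distance from their group centre, 0.120 ± 0.030 at diagnosis and 0.123 ± 0.035 at relapse (SD, n = 35 each). The difference was 0.0031 (two-sided permutation p = 0.689). The RNA degradation index was 4.58 ± 0.31 at diagnosis and 4.59 ± 0.44 at relapse (SD), a difference of 0.011 ± 0.091 (two-sided permutation p = 0.907). Its GAPDH part differed by 0.12 (p = 0.138) and its ACTB part by -0.094 (p = 0.579).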

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

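The permutation of arrays, the array brightness covariate, leaving out the 6 bright relapse arrays, leaving out the 8 arrays of low B-precursor or MHC class II score, the fits leaving out an array for lists, and fry combined with another choice were chosen after the data were seen; the other settings were planned. The count of genes past adjusted p 0.1 stayed at 0 in both directions under quantile normalization, median centring, no pseudocount, no filter, the filter at the 75th percentile, the mean of probe sets, a threshold of 0.05, the Wilcoxon test, the outlying array left out, the brightness covariate, the 8 low-score arrays left out and the shared-number fits. It became 7 higher and 4 lower with the pseudocount at the 25th percentile, 6 and 3 with array weights, 6 and 3 with the RNA degradation index as a covariate, and 1 and 1 with the marker scores as covariates. With all probe sets tested, 1 lower probe set passed, and without the 6 bright relapse arrays 1 higher and 0 lower genes did. Leaving out each array in turn gave 0 to 10 higher and 0 to 7 lower genes, and 14 to 17 lists. Calls appeared without diagnosis replicate 38 (10 higher, 7 lower), 3 (7, 3), 13 (6, 5), 29 (6, 2), 31 (2, 2) and 4 (0, 1), and without relapse replicate 60 (4, 1), 12 (3, 0), 76 (2, 1) and 70 (1, 0). With a smallest adjusted p of 0.122, the single-gene calls sat near the threshold, and the cause of each change was not tested.

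Of the 27 lists, camera at the preset correlation called 11 to 16 across the settings other than leaving out 1 array, against 0 with an estimated correlation, 4 with fry and 4 by permutation of the arrays. Fry called 5 with quantile normalization, 6 with no filter, 5 with the outlying array left out, 6 with the marker scores as covariates, 4 without the 6 bright relapse arrays and 2 with the brightness covariate, which kept the mitosis and granulocyte lists; the permutation without the 6 bright relapse arrays called 3. In the 70 fits without 1 array, fry called the mitosis, oxidative phosphorylation and granulocyte lists in 70 and the glucocorticoid list in 54; camera called the B-precursor list in 67 and the T and NK list in 33. The sign of the mean turned for heat shock genes with the marker scores (-0.0157) and brightness (-0.0072), cholesterol synthesis genes with the marker scores (0.0279), anti-apoptotic genes with brightness (0.0019), and MHC class II (4e-04) and glycolysis genes (-0.0069) without the outlying array. Without the 6 bright relapse arrays it turned for stem and progenitor markers (0.0687), glycolysis genes (-0.008) and heat shock genes (-0.052), and CD34 turned to -0.0314. Without the 8 low-score arrays 16 lists passed camera at the preset correlation, with the adhesion and migration list gained (-0.1685, adjusted p = 0.0438) and the B-precursor list lost; MHC class II turned to 0.028, CD3D to -0.0234, DNTT to 0.3625 and MSH6 to 0.0788. The RNA degradation index turned to -0.0939 with ACTB alone. Among named genes, CD34 turned to -0.0053 with quantile normalization, -0.0013 with no pseudocount, -0.0134 with array weights, -0.1243 with the difference in medians beside the Wilcoxon test and -0.0648 with the marker scores. ASNS turned to 0.0152 with the pseudocount at the 25th percentile, 0.4319 with the difference in medians and 0.1088 with the marker scores. The difference in medians was 0.4858 for DNTT and 0.1766 for MSH6, and the marker scores gave -0.1505 for HBD and -0.1256 for MPO. Leaving out the outlying array gave -0.0196 for CD3D, 0.047 for DNTT and 0.016 for MSH6. The cause of these turns was not tested.

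No label states which arrays are of the same patient, and 2 readings of the label numbers were tried as a replicate block. For the 10 numbers that occur in both groups, the deviations of same-numbered arrays correlated from -0.1846 to 0.276, with 2 of 10 over 0.1 and 0 diagnosis arrays correlating best with their own number. The block gave 0 higher and 0 lower genes and 13 lists, as did the same 20 arrays without it. Both gave CD24 1.5849, CD3D -1.6384, CD72 0.772, CD79A 0.2678, CD9 0.2937, DNTT 1.3958, DUSP1 0.478, HBD -0.0116, MSH6 0.7036, NFKB1 0.3512, NR3C1 0.169, RRM2 -0.258, TNF 0.0119, TRIM22 0.1286 and TSC22D3 0.275. For lists, both gave glucocorticoid-induced 0.031, B-precursor 0.9378, mature B and plasma cell 0.1603, erythroid -0.0197, MHC class II 1.157 and glycolysis -0.043. Without the block, the B-precursor and MHC class II lists had camera adjusted p = 1.54e-07 and 2.61e-06. Those 20 arrays hold all 6 bright relapse arrays. They also hold the 3 diagnosis arrays of low B-precursor or MHC class II score, but none of the 5 such relapse arrays. The smaller number of arrays is part of the construction of these fits.

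Taking the relapse number minus 43 as the diagnosis number, for diagnosis numbers from 17 on as fixed in advance, gave 20 pairs with correlations from 0.0416 to 0.6812, of which 16 were over 0.1; 13 of 20 diagnosis arrays correlated best with their own number. The median correlation was 0.3397 for these pairs, against -0.0104 for the other pairs of a diagnosis and a relapse array. The condition set in advance, that every pair exceed 0.1, was not met, so the numbering is a hint from the data about patient pairing and not a paired result. This replicate block gave 49 higher and 81 lower genes and 13 lists, against 1 higher and 0 lower genes and 11 lists without the block on the same arrays. Both fits gave ASNS 0.0322, CD34 -0.1894, NT5C2 -0.0997, PSMD4 -0.0013 and TNFAIP3 0.0083, and for lists DNA repair -0.071, anti-apoptotic 0.1061, MYC targets -0.0434 and NF-kB 0.1675. The number of arrays limits the precision throughout, and dim probe sets near the background are compressed by the pseudocount.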

Other observations

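After the genes of smallest p were seen, 3 gene families were chosen and tested over all their tested members. The sign looked for was taken from those genes and written down before the family means were computed. The 131 tested zinc-finger genes named ZNF, most of which encode DNA-binding repressors, had a mean log2 difference of -0.1195 ± 0.042 (SE; 96 of 131 negative, 15 negative with an unadjusted p under 0.05; two-sided permutation p = 0.00513, adjusted over the 3 families 0.0154). ZNF443 differed by -0.73 ± 0.22, ZNF14 by -0.53 ± 0.18 and ZNF211 by -0.52 ± 0.17. The 17 canonical and linker histone genes had a mean of -0.2704 ± 0.12 (13 of 17 negative, 5 with an unadjusted p under 0.05; two-sided permutation p = 0.0237, adjusted 0.0356). H1-2 differed by -0.94 ± 0.25, H2AC6 by -0.81 ± 0.23, H1-10 by -0.76 ± 0.26 and H2BC12 by -0.68 ± 0.28. Apart from H1-2, these single genes were named outside the rule, after their values were seen. The 40 mitochondrial ribosomal protein genes had a mean of 0.1211 ± 0.078 (31 of 40 positive; two-sided permutation p = 0.124), which does not settle whether that family lies higher. With array brightness as a covariate the ZNF mean was -0.11 ± 0.042 and the histone mean -0.26 ± 0.12, and both kept their sign with quantile normalization (-0.12 and -0.26) and median centring (-0.11 and -0.26). With a correlation estimated by camera, p was 0.019 for the ZNF genes and 0.0516 for the histones. These families and their signs were picked from the same arrays, and H1-2, among the genes seen first, stayed in its family. The adjustment over 3 families does not cover that choice, so both shifts are hypotheses.

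A total of 3 patterns were weighed against technical explanations; the array brightness covariate, the test of T and NK markers against the other cell types and the fits without the 6 bright relapse arrays were chosen after the results were seen. The RNA degradation index was meant as one such test, with a bound written before it was run, but its GAPDH and ACTB parts did not correlate over the arrays (r = -0.049). It is therefore no common measure of RNA quality, and degradation stays open for all 3 patterns.

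The higher mitosis and G2/M genes at relapse had a mean difference of 0.42 ± 0.13, which was 0.3725 ± 0.13 with array brightness as a covariate and 0.3315 ± 0.14 with the T and NK, granulocyte, monocyte and erythroid marker scores as covariates. In both cases it kept over 0.5 of its size and lay more than 2 SE from 0. This argues against the signal level of the deposited values or the content of those cells as the whole cause. The difference was 0.44 ± 0.12 without the 6 bright relapse arrays, and 0.4165 with the RNA degradation index, which cannot decide. Within each group the mitosis score did not follow the erythroid, granulocyte or B-precursor scores (6 relations, Pearson r from -0.047 to 0.16, adjusted p = 0.91 each). A higher share of dividing cells in relapse marrow, or a higher level per dividing cell, may underlie the shift and could not be separated here.

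The immediate early, glucocorticoid-induced and NF-kB genes together lay lower at relapse by a mean of -0.37 ± 0.14. The difference was -0.2786 ± 0.13 with array brightness and -0.472 ± 0.14 with the marker scores as covariates. This argues against the signal level of the deposited values or the content of those cells as the whole cause. Without the 6 bright relapse arrays it was -0.3537 ± 0.15, and with the RNA degradation index -0.3719, which cannot decide. The highest immediate early and glucocorticoid scores were in diagnosis replicates numbered up to 16, led by replicates 6 (2.76) and 16 (1.63). In diagnosis replicates numbered from 17 on, the scores reached at most 0.72 and 0.75. Diagnosis arrays of low label number thus weigh heavily in the lower level of these genes at relapse. These genes also respond to cell handling, thawing and steroid exposure, none of which the labels record, so a difference in sample handling or in treatment before sampling may account for them and was not tested.

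The granulocyte, monocyte and erythroid markers together lay higher at relapse by a mean of 0.51 ± 0.21. It was 0.6052 ± 0.21 with array brightness as a covariate, 0.5158 ± 0.22 without the 6 bright relapse arrays and 0.5079 with the RNA degradation index, which cannot decide. If a lower share of leukaemic cells raised the markers of all other cell types alike, the T and NK markers would rise as much. Instead the T and NK markers, 12 tested of 25 listed, lay 0.68 below the mean of the 3 lists (-0.6758 ± 0.22, two-sided permutation p = 0.00266). The lists were chosen for this contrast after their directions were seen, and that p does not allow for the choice. Taken alone, the T and NK markers had a mean of -0.16 ± 0.16 (two-sided permutation p = 0.317). The absence of a T and NK rise argues only weakly against such an even rise. It would not do so if leukaemias of T lineage, which the labels would not show, supplied part of the T cell markers. Diagnosis replicates 4, 12 and 38 and relapse replicates 39, 58 and 81 had B-precursor scores from -3.14 to -1.84. Their T and NK scores ran from 0.34 to 1.29, and whether they are of T lineage was not tested. A lower share with an uneven rise of the other cells stays open, and the B-precursor markers had a mean of -0.28 ± 0.27. More myeloid and erythroid cells in relapse marrow may underlie the shift.

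Chance was examined with 100 splits of the arrays into groups of 35, the real one included. For genes past adjusted p 0.1 the real count was 0, so that all 100 reached it and the count decides nothing (highest other 293, median of the others 0). For genes with an unadjusted p under 0.05, 11 of 100 gave at least 637 (highest other 1247), so chance could not be excluded. For lists past camera at the preset correlation, 3 of 100 gave at least 16 (highest other 16, median of the others 8). That share lies under the bound of 0.05 set for these counts. The counts were not adjusted for one another, and other splits reached 16 too, so chance was not excluded.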
